A study of Mus musculus with 9 samples.

How the data were processed

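Gene expression was measured by RNA sequencing in 9 mouse tumours, 3 from each of 3 treatment groups. Per the labels' protocols, polyadenylated RNA was made into strand-marked (dUTP) libraries and sequenced in paired reads of 150 bases on an Illumina NovaSeq. The submitters' processing notes name fastp, StringTie and edgeR, without versions, order or settings. The aligner, genome build and annotation are not given in the sources used here, so genes are identified by symbol and Ensembl ID and no coordinates are printed. The values the authors deposited are FPKM, fragments scaled by transcript length and by the mapped total, for 32761 genes, although the table is presented as raw counts. Column totals ranged from 3.32e+05 to 3.73e+05 FPKM, and between 23575 and 26298 genes were above 0 in a library.

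The tests fixed before the data were examined assumed counts, and the edgeR quasi-likelihood test named there was not run. Because the values are FPKM, limma 3.58.1 in R 4.3.3 was used instead, with empirical Bayes moderation, a mean-variance trend and robust variance, on log2(FPKM + 0.5). This scale understates the change of genes with low values. The groups, the comparisons, the single fit of all 9 libraries with 6 residual degrees of freedom and the Benjamini-Hochberg threshold of 0.05 were kept as fixed. Genes with a mean of at least 0.5 FPKM were tested, 15353 in all. FPKM were used as deposited, with no further scaling. In the text, "rose" and "fell" refer to this threshold in this fit, adjusted p-values are limma's, and means are FPKM with the SD over 3 libraries.

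A search for whole-fragment steps in low values of genes with 1 transcript gave estimates of 1.47e+07 to 2.18e+07 fragments per library. Only 8.76% to 10.8% of those low values lay on whole fragments, so the reads were not recovered and the depth is an estimate. No interval that needs a depth is given for single values.

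The 45 gene lists were written before the data were examined, from textbook markers of immune, vascular, stromal, liver and other cell types and of pathways. Of their 930 symbols, 918 were found. Each list was tested with camera in limma at a preset correlation of 0.01, adjusted over the lists in each comparison, and again with an estimated correlation and with fry. fry asks whether a list's genes move one way on balance and does not compare the list with other genes.

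Named genes followed a rule fixed before the data were examined: the 8 largest rises and 8 largest falls per comparison among well-expressed genes whose groups did not overlap, up to 4 leading members of each list that passed and up to 2 of each that did not, and a fixed set of tumour, immune, vessel and stress genes. The rule's floor of 2 for mean log2 CPM was applied to mean log2(FPKM + 0.5). Only a selection of these genes is named in the text. A gene outside the rule is said to be so where it is named. Symbols are shared by 133 genes, which were kept apart by ID.

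The limma step was tested on simulated data for the 15353 genes with 200 genes changed. For Co+Len@OVA+anti-PD1 against Control it recovered 38.8% of 1.5-fold, 77.6% of 2-fold and 90.9% of 4-fold changes, with 11 false calls. For Lenvatinib+anti-PD1 against Control the shares were 40.3%, 73.1% and 95.5%, with 6 false calls, and between the treatments 29.9%, 68.7% and 97.0%, with 7. These simulations assumed 3 independent libraries per group.

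Alternatives planned beforehand were other scale factors, other filters, fits of 2 groups, a replicate block, a 2-fold minimum, and leaving out each library. DESeq2 and limma-voom were planned and not run, since they need counts. Other pseudocounts, a plain variance model, rescaling without mitochondrial genes and fits to pairs of libraries per group were added after seeing the data. So were the marker lists of neural and corneal tissue.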

Results

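Tumours were taken on day 14 from mice carrying Hepa1-6-luc tumours in the liver, a luciferase-marked mouse hepatoma line. Of the 6 treatment groups in the study, 3 were sequenced, with 3 tumours each. They were an untreated Control, free lenvatinib with an antibody against PD1, and a nanocluster labelled Co+Len@OVA with the same antibody. Lenvatinib inhibits the VEGF and FGF receptor kinases, and PD1 is an inhibitory receptor of T cells. The antibody was given at 50 µg per injection every 4 days, and the nanocluster (2 mg/mL) or free drug every 3 days. The 2 comparisons with Control ask how each treatment altered the tumour, and the comparison between treatments asks how Co+Len@OVA differed from free lenvatinib. The labels do not say what Co stands for. Formulation, dose and the other parts named in the nanocluster label cannot be told apart in this comparison. No sequenced group received the drug or the antibody alone.

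The third library of each group was close to a weighted mean of the other 2. Among genes that differed over 4-fold between libraries 1 and 2, the third library lay between them for 96.8% of 278 genes in Co+Len@OVA+anti-PD1, 97.2% of 284 in Lenvatinib+anti-PD1 and 94.0% of 350 in Control. Around the best weighted mean, the third library scattered by a median absolute deviation of 0.039, 0.042 and 0.049 on the log2 scale in these groups, over 155 to 179 well-covered genes. Libraries 1 and 2 scattered by 0.073 to 0.231 around the best mean of the others in their group. In 20 simulations without any group effect and with library 3 a mixture of the others, 24.7% of genes had p under 0.05 and a mean of 1138 genes were called, against 5.00% and 0.10 with library 3 independent. The p-values from 9 libraries are therefore too small if the third libraries are not independent. For each comparison the counts from libraries 1 and 2 alone are also given, for all genes and for the members of each list described, from a fit chosen after seeing the data that has 3 residual degrees of freedom.

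**Figure D1:**
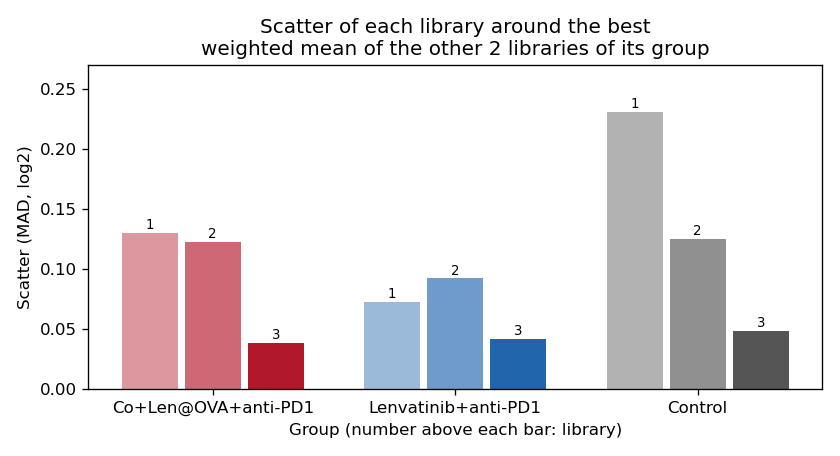
Bars give the scatter (median absolute deviation, log2 scale) of each library, numbered above its bar, around the best weighted mean of the other 2 libraries of its group. The third library has the lowest bar in each group, at 0.039, 0.042 and 0.049.

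In Co+Len@OVA+anti-PD1 tumours, genes of T cells, cytotoxic lymphocytes and interferon responses were higher than in Control, and genes of mature hepatocytes were lower. With an estimated correlation none of these lists passed (adjusted p = 0.669 for T cells, 0.660 for cytotoxic lymphocytes, 0.613 for both interferon lists and 0.384 for hepatocytes). Control library 1 stood apart from the other controls, lowest in its group by over 2-fold for 725 genes against 170 and 17 for libraries 2 and 3. It had 3.23 FPKM of Cd8a against 12.1 and 9.53, and 3386 of Alb against 1686 and 2285. Cd8a, the CD8 co-receptor of cytotoxic T cells, rose from 8.29 ± 4.57 to 36.0 ± 6.03 FPKM (SD, n = 3; log2 fold change 2.22 ± 0.40 SE, adjusted p = 0.00496). Gzmb and Prf1, which encode the cytotoxic granule proteins granzyme B and perforin, rose by 2.51 and 2.49 on the log2 scale (adjusted p = 0.00469 and 0.00987). Alb, which encodes serum albumin, fell from 2452 ± 862 to 773 ± 139 FPKM (adjusted p = 0.00229). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose from 76.6 ± 28.8 to 409 ± 38.1 FPKM (adjusted p = 0.000650).

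Among the interferon gamma response and chemokine genes, 24 of 28 rose and none fell (26 rose when adjusted over the list alone), with a median log2 fold change of 1.46 (camera adjusted p = 1.14e-09, and adjusted p = 0.613 with an estimated correlation). Ido1 rose by 2.25 and Gbp10 by 2.30 on the log2 scale, and the T cell attracting chemokines Cxcl9 and Cxcl10 by 1.74 and 2.33. Of the type I interferon response genes, 26 of 34 rose (30 adjusted over the list alone; median 1.11; adjusted p = 1.62e-08, and adjusted p = 0.613 with an estimated correlation). Bst2 rose from 105 ± 7.67 to 233 ± 3.13 FPKM. Of the MHC class I presentation genes, 19 of 23 rose (21 adjusted over the list alone; adjusted p = 1.22e-07, and adjusted p = 0.466 with an estimated correlation), among them the immunoproteasome subunits Psmb8 and Psmb9. T cell markers rose in 23 of 27 cases (26 adjusted over the list alone; median 1.49; adjusted p = 8.86e-07, and adjusted p = 0.669 with an estimated correlation), and cytotoxic lymphocyte genes in 14 of 18 (14 adjusted over the list alone; median 1.67; adjusted p = 3.01e-05, and adjusted p = 0.660 with an estimated correlation). Of the pro-inflammatory macrophage genes 11 of 16 rose (13 adjusted over the list alone; adjusted p = 1.32e-05, and adjusted p = 0.613 with an estimated correlation), with Ccl4 at 35.6 ± 1.41 against 4.79 ± 1.76 FPKM. The components of the cGAS-STING pathway, which senses cytosolic DNA, did not pass as a list (adjusted p = 0.176). Cgas was at 0.82 ± 0.19 against 0.36 ± 0.24 FPKM (adjusted p = 0.0728), and Sting1 at 36.0 ± 3.37 against 28.5 ± 5.09 FPKM (adjusted p = 0.0671), and without Control replicate 2 both passed (adjusted p = 0.0482 and 0.0205). In libraries 1 and 2 alone these member counts fell to 2 interferon gamma, 1 type I interferon and 1 MHC class I gene risen, and to 0 T cell, 0 cytotoxic and 0 pro-inflammatory macrophage genes in limma (18, 14 and 10 rose at an unadjusted p under 0.05). Without Co+Len@OVA+anti-PD1 replicate 3, 14 T cell markers rose instead of 23.

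Of the 38 mature hepatocyte genes tested, 34 fell and none rose (35 fell when adjusted over the list alone), with a median log2 fold change of -2.26 (adjusted p = 2.89e-23, and adjusted p = 0.384 with an estimated correlation). Ahsg, which encodes the plasma protein fetuin-A, was at 8.36 ± 2.08 against 289 ± 130 FPKM, with 429, 171 and 267 in the 3 controls. Whether the pieces held different amounts of liver tissue was not tested for this comparison. Of the acute phase and complement genes 20 of 25 fell and 4 rose (20 and 4 adjusted over the list alone; median -2.48; adjusted p = 1.14e-09, and adjusted p = 0.384 with an estimated correlation). Afp, the fetal liver protein used as a hepatoma marker, fell from 404 ± 35.2 to 237 ± 3.90 FPKM. Of the 34 HIF and hypoxia targets, 16 fell and 4 rose (17 and 4 adjusted over the list alone; median -0.30; adjusted p = 1.74e-06, and adjusted p = 0.284 with an estimated correlation). Car9, a carbonic anhydrase of hypoxic cells, fell by 1.10 on the log2 scale and Ddit4 fell by 1.88. The metallothioneins Mt1 and Mt2, which bind metal ions, fell by 1.81 and 1.67 on the log2 scale, while the metal response list did not pass (adjusted p = 0.0677). Of the cell cycle genes 21 of 40 rose (23 adjusted over the list alone; adjusted p = 4.60e-05, and adjusted p = 0.716 with an estimated correlation). Erythroid and platelet genes, measured as markers of blood, rose in 7 of 9 cases and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0377, and adjusted p = 0.669 with an estimated correlation), with the haemoglobin gene Hbb-bs at 798 ± 137 against 140 ± 45.3 FPKM. With libraries 1 and 2 alone 6 hepatocyte, 3 acute phase and 1 HIF gene fell, and 0 cell cycle and 0 erythroid genes passed (15 and 7 rose at an unadjusted p under 0.05). Without Co+Len@OVA+anti-PD1 replicate 3, 13 cell cycle genes rose instead of 21.

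In all, 5155 of 15353 genes passed, 3209 higher and 1946 lower in Co+Len@OVA+anti-PD1. With libraries 1 and 2 alone 80 passed, 17 higher and 63 lower, and all 80 were among the 5155. Leaving out Co+Len@OVA+anti-PD1 replicate 3 gave 1611 higher and 1238 lower. Cd8a (log2 fold change 2.41, adjusted p = 0.123), Gzmb (2.76, 0.114), Alb (-1.66, 0.114) and Hmox1 (2.62, 0.0660) did not pass with libraries 1 and 2 alone, while Ahsg did (0.0348). The median log2 fold change of all genes was 0.13, and median-of-ratios scaling gave 2209 higher and 2702 lower, upper quartile scaling 1637 and 2997. The largest rises under the naming rule were, in order, Cfd, Igkv12-46, Car3 and Ighv9-3. Cfd and Car3 belong to the adipocyte list, and the others are immunoglobulin segments. Cfd varied within the group, at 141, 22.4 and 79.7 FPKM against 0.763, 0 and 4.09 in Control.

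**Figure D2:**
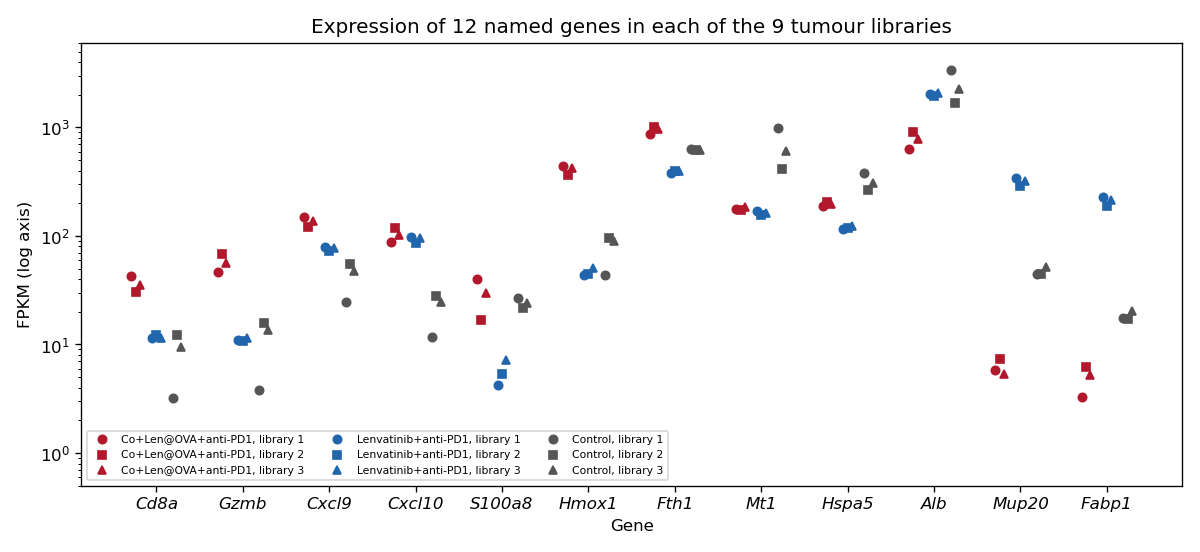
Each point is the FPKM (log axis) of a named gene in a library, with group by colour and library by shape. Hmox1 lies at 409 ± 38.1 FPKM in Co+Len@OVA+anti-PD1, against 46.3 ± 3.96 in Lenvatinib+anti-PD1 and 76.6 ± 28.8 in Control (SD, n = 3).

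In Lenvatinib+anti-PD1 tumours, hypoxia targets and neutrophil genes were lower than in Control and genes of cholesterol synthesis were higher. With an estimated correlation the neutrophil (adjusted p = 0.161) and cholesterol synthesis (0.107) lists did not pass. Of the 34 HIF and hypoxia targets 21 fell and none rose (22 fell when adjusted over the list alone), with a median log2 fold change of -0.55 (camera adjusted p = 1.55e-11, and adjusted p = 0.04997 with an estimated correlation). Adm, which encodes the vasodilator adrenomedullin, fell from 4.95 ± 0.51 to 1.02 ± 0.08 FPKM (adjusted p = 4.79e-05), and Slc2a1, a glucose transporter, from 114 ± 18.6 to 59.6 ± 4.28 FPKM (adjusted p = 0.00149). Of the neutrophil markers 14 of 19 fell (14 adjusted over the list alone; median -1.48; adjusted p = 4.17e-09, and adjusted p = 0.161 with an estimated correlation), including S100a8, at 5.59 ± 1.49 against 24.4 ± 2.55 FPKM. Arg1, an arginase of alternatively activated macrophages and hepatocytes, fell from 110 ± 3.90 to 33.4 ± 2.42 FPKM (adjusted p = 5.74e-05).

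Of the 27 cholesterol and fatty acid synthesis genes 17 rose and none fell (18 rose when adjusted over the list alone; median 0.44; adjusted p = 2.70e-07, and adjusted p = 0.107 with an estimated correlation), with Hmgcs1 at 34.8 ± 1.38 against 19.4 ± 1.47 FPKM. Of the mature hepatocyte genes 13 of 38 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.81; adjusted p = 0.00176, and adjusted p = 0.869 with an estimated correlation), and 25 rose without Control replicate 1. Cyp2a5 and Fabp1, genes of drug and fatty acid handling in hepatocytes, were at 131 ± 7.32 against 9.53 ± 2.40 and 210 ± 19.7 against 18.2 ± 1.77 FPKM. The amount of liver tissue in the pieces was not tested here either. Of the unfolded protein response genes 10 of 23 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.000440, and adjusted p = 0.161 with an estimated correlation), with the chaperone Hspa5 at 120 ± 3.79 against 319 ± 58.3 FPKM. Of the interferon gamma response genes 14 of 28 rose (17 rose and 1 fell adjusted over the list alone; adjusted p = 2.30e-05, and adjusted p = 0.869 with an estimated correlation), and Cxcl10 was at 92.7 ± 6.17 against 21.3 ± 8.52 FPKM. Of 27 T cell markers 0 passed in limma, also 0 at an unadjusted p under 0.05 (adjusted p of the list 0.803), and Cd8a was at 11.7 ± 0.40 FPKM (adjusted p = 0.267). Of the tip cell and VEGF signalling genes 7 of 28 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.00393, and adjusted p = 0.869 with an estimated correlation), including Pgf, which encodes placental growth factor, at 0.46 ± 0.12 against 1.53 ± 0.17 FPKM. Of 22 endothelial cell markers 0 passed (1 rose at an unadjusted p under 0.05). Mitochondrially encoded mRNAs rose in 9 of 13 cases (12 adjusted over the list alone; adjusted p = 6.05e-07, and adjusted p = 0.863 with an estimated correlation), and mitochondrial genes held 16.3% to 17.9% of the FPKM total in this group against 11.1% to 13.2% in Control. Skeletal and heart muscle genes, measured as markers of neighbouring tissue, had a median FPKM of 132 and 53.2 in libraries 2 and 3 of this group and at most 2.42 in the other 7. Of them 11 of 19 rose (18 adjusted over the list alone; adjusted p = 7.42e-05, and adjusted p = 0.869 with an estimated correlation). The fit of libraries 1 and 2 had 3 hepatocyte genes and 1 interferon gamma gene that rose, and 1 hepatocyte, 1 HIF and 1 tip cell gene that fell. In that fit 0 neutrophil, cholesterol synthesis, unfolded protein response, mitochondrial and muscle genes passed in limma (12, 15, 8, 9 and 7 moved in the direction of their list at an unadjusted p under 0.05). Leaving out Lenvatinib+anti-PD1 replicate 3 left 10 cholesterol synthesis and 9 interferon gamma genes risen and 6 unfolded protein response and 2 tip cell genes fallen, and leaving out Control replicate 3 also left 6 unfolded protein response genes. Leaving out Control replicate 1 gave 15 tip cell genes fallen. Of the muscle genes 0 passed in limma without Lenvatinib+anti-PD1 replicate 2 or 3, Control replicate 1 or 2, or Co+Len@OVA+anti-PD1 replicate 3, and 18 rose without Lenvatinib+anti-PD1 replicate 1.

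In all, 3636 genes passed, 2120 higher and 1516 lower in Lenvatinib+anti-PD1. With libraries 1 and 2 alone 53 passed, 33 higher and 20 lower, all among the 3636. Leaving out Control replicate 1 gave 2374 higher and 2679 lower, so the majority turned, Lenvatinib+anti-PD1 replicate 3 1061 and 896, replicate 2 of that group 1373 and 1037, and Control replicate 3 1303 and 835. Upper quartile scaling gave 1292 higher and 2090 lower. In libraries 1 and 2, Cyp2a5 (adjusted p = 0.0190), Fabp1 (0.0307), Adm (0.0377) and Arg1 (0.0387) passed, and S100a8 (log2 fold change -2.24, adjusted p = 0.122, against -2.05 in 9 libraries) and Slc2a1 (-0.97, 0.124, against -0.91) did not.

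Between the treatments, mature hepatocyte genes were far lower in Co+Len@OVA+anti-PD1, and the lists of T cells, B cells, neutrophils and pan-macrophage markers were higher. With an estimated correlation none of these lists passed (adjusted p = 0.480 for hepatocytes, B cells and neutrophils, and 0.525 for T cells and pan-macrophage markers). Of the 38 hepatocyte genes 34 fell and 1 rose (34 and 1 adjusted over the list alone), with a median log2 fold change of -3.89 (camera adjusted p = 5.00e-24, and adjusted p = 0.480 with an estimated correlation). Mup20, a major urinary protein made by hepatocytes, was at 6.16 ± 1.05 against 315 ± 26.6 FPKM (adjusted p = 4.19e-07), and Fabp1 at 4.92 ± 1.53 against 210 ± 19.7 FPKM (adjusted p = 2.74e-06). Hmox1 was at 409 ± 38.1 against 46.3 ± 3.96 FPKM, 8.74-fold higher on the log2(FPKM + 0.5) scale (adjusted p = 0.000157). Fth1, the ferritin heavy chain that stores iron, was at 955 ± 71.4 against 394 ± 10.1 FPKM (adjusted p = 1.45e-05). Mt1 was at 180 ± 6.27 against 163 ± 7.02 FPKM (adjusted p = 0.704). Its values did not overlap between the treatments, but the spread in this fit includes the controls, at 991, 418 and 602 FPKM.

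T cell markers rose in 20 of 27 cases (27 adjusted over the list alone; median 1.36; adjusted p = 4.73e-07, and adjusted p = 0.525 with an estimated correlation). Gzmb was at 57.0 ± 10.4 against 11.1 ± 0.38 FPKM (adjusted p = 0.00720). Of the immune checkpoint and exhaustion genes 12 of 18 rose (16 adjusted over the list alone; adjusted p = 2.58e-05, and adjusted p = 0.512 with an estimated correlation), and Tigit, an inhibitory receptor of lymphocytes, was at 96.8 ± 3.99 against 38.1 ± 1.40 FPKM. In the Control libraries Tigit did not follow Cd8a, at 65, 53 and 54 FPKM where Cd8a was at 3.2, 12 and 9.5. The cell source of Tigit was not tested. B cell and plasma cell markers rose in 13 of 18 cases (14 adjusted over the list alone; adjusted p = 5.33e-07, and adjusted p = 0.480 with an estimated correlation), led by the immunoglobulin genes Igkc and Ighg2c. Neutrophil markers rose in 15 of 19 cases and fell in 1 (17 and 1 adjusted over the list alone; adjusted p = 9.76e-06, and adjusted p = 0.480 with an estimated correlation), and pan-macrophage markers in 13 of 21 (18 adjusted over the list alone; adjusted p = 2.87e-06, and adjusted p = 0.525 with an estimated correlation). Of the tip cell and VEGF signalling genes, which mark growing vessels, 18 of 28 rose (23 adjusted over the list alone; median 1.09; adjusted p = 2.74e-06, and adjusted p = 0.512 with an estimated correlation), with Angpt2 at 7.96 ± 0.90 against 1.37 ± 0.33 FPKM. Of the cholesterol and fatty acid synthesis genes 21 of 27 fell (23 adjusted over the list alone; median -0.49; adjusted p = 1.81e-12, and adjusted p = 0.0522 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone; adjusted p = 3.94e-07, and adjusted p = 0.481 with an estimated correlation). Erythroid and platelet genes rose in 7 of 9 cases and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00421, and adjusted p = 0.512 with an estimated correlation), with Hbb-bs at 798 ± 137 against 84.8 ± 38.4 FPKM. The muscle list passed as lower (adjusted p = 8.33e-05, and adjusted p = 0.550 with an estimated correlation), while 0 of its 19 genes passed singly in limma (16 fell at an unadjusted p under 0.05). Of the type I interferon response genes 12 of 34 rose and 0 fell (20 rose when adjusted over the list alone; adjusted p = 2.58e-05, and adjusted p = 0.550 with an estimated correlation). Of the interferon gamma response genes 10 of 28 rose and 0 fell (13 adjusted over the list alone; adjusted p = 0.000113, and adjusted p = 0.574 with an estimated correlation). Within these lists Cxcl10 (103 ± 16.1 against 92.7 ± 6.17 FPKM, adjusted p = 0.731) and Isg15 (25.7 ± 3.94 against 16.9 ± 1.32 FPKM, adjusted p = 0.0624) did not pass, although Isg15 did without Control replicate 1 (adjusted p = 0.00620) or 2 (0.0414). The regulatory T cell (adjusted p = 0.177), dendritic cell (0.106), cGAS-STING (0.110) and Kupffer cell (0.454) lists did not pass. With libraries 1 and 2 alone 23 hepatocyte and 2 cholesterol synthesis genes and 1 erythroid gene fell, and 1 hepatocyte, 5 B cell, 1 checkpoint, 1 pan-macrophage and 1 tip cell gene rose. In that fit 0 T cell, neutrophil, mitochondrial, type I interferon and interferon gamma genes passed in limma (17, 13, 9, 7 and 7 moved in the direction of their list at an unadjusted p under 0.05). Leaving out Co+Len@OVA+anti-PD1 replicate 3 left 6 T cell, 5 checkpoint, 9 tip cell, 5 type I interferon and 6 interferon gamma genes risen, and 12 cholesterol synthesis and 8 mitochondrial genes fallen. Leaving out Control replicate 1 gave 27 T cell, 21 pan-macrophage, 26 type I interferon and 26 interferon gamma genes risen.

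In all, 4507 genes passed, 2657 higher and 1850 lower in Co+Len@OVA+anti-PD1. With libraries 1 and 2 alone 365 passed, 68 higher and 297 lower, all among the 4507. Leaving out Lenvatinib+anti-PD1 replicate 1 gave 1372 higher and 1528 lower, so the majority turned, Lenvatinib+anti-PD1 replicate 3 1391 and 1134, Co+Len@OVA+anti-PD1 replicate 3 1218 and 1163, and Control replicate 1 4224 and 2368. Hmox1 (adjusted p = 0.0291), Fth1 (0.0210), Mup20 (0.00164), Fabp1 (0.00586), Tigit (0.0192) and Igkc (0.0155) passed with libraries 1 and 2 alone. Gzmb (log2 fold change 2.33, adjusted p = 0.154, against 2.30 in 9 libraries) and Angpt2 (2.17, 0.0607, against 2.18) did not pass in that fit. Median-of-ratios scaling gave 2076 higher and 2334 lower, and upper quartile scaling 1914 and 1979.

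**Figure D3:**
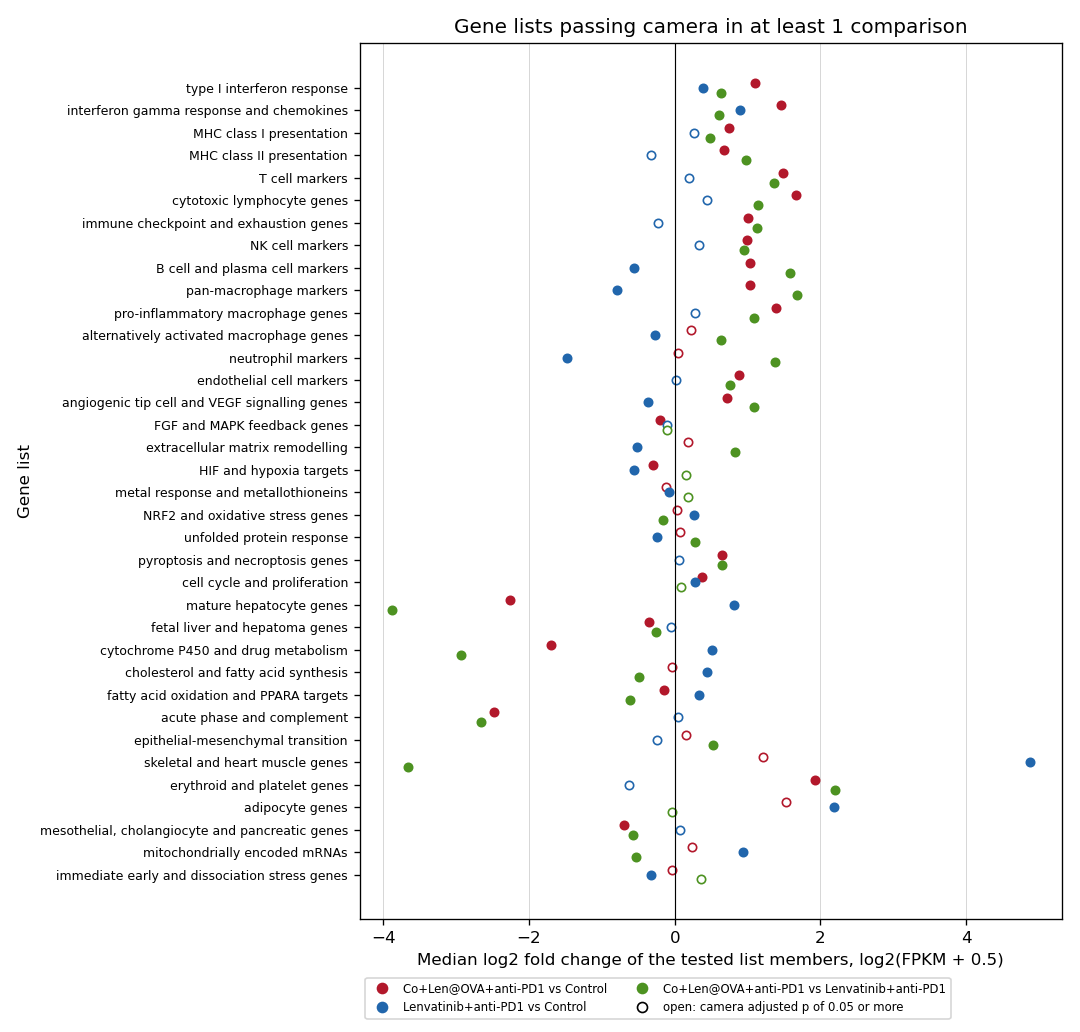
Points give the median log2 fold change, on log2(FPKM + 0.5), of the tested members of each gene list that passed camera in at least 1 comparison, with the comparison by colour and open points for an adjusted p of 0.05 or more. Mature hepatocyte genes lie at -2.26, 0.81 and -3.89 in the 3 comparisons.

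Over the 3 groups together 6935 genes differed (limma's F-test), and 305 with libraries 1 and 2 alone. Both treatments differed from Control in the same direction for 1652 genes, 945 higher and 707 lower, and in opposite directions for 347. Median-of-ratios scaling gave 696 shared genes higher and 962 lower, and upper quartile scaling 403 and 1109. With libraries 1 and 2 alone 14 genes were shared in direction and 4 were opposite. Lists of these sizes drawn independently would share 443 higher and 192 lower genes, and 100 simulations of unchanged groups of independent libraries against the same controls gave a mean of 0.02. Almost no gene passes in such simulations, so the 0.02 cannot show how many shared genes the controls add where groups differ. With library 3 of each group simulated as a mixture of the others, 20 simulations without a group effect gave a mean of 361 shared genes. Across genes, which are not independent replicates, the fold changes of both treatments had a correlation of 0.18 against a simulated 0.50. Their covariance was 0.072 against 0.031 simulated with independent libraries, a difference of 0.040, and 0.097 simulated with the mixtures. The independent simulations took each gene's spread from the fit of all 9 libraries, the mixtures from libraries 1 and 2. The 2 simulated covariances therefore differ by more than the mixing, and the 0.040 is not a measured excess over shared controls. The 3 controls are too few to give each comparison at least 2, so they were not split. Part of the excess of shared genes may come from the shared controls. For the covariance this may be all of it, since 0.072 is below the 0.097 simulated with the mixtures. Camera called 24, 21 and 30 of the 45 lists in the 3 comparisons and 24, 20 and 30 with libraries 1 and 2 alone. The third libraries lay near a mean of the other 2, so leaving them out changes the fold changes little. The likeness of these counts is therefore no separate evidence of stability. Other splits of the 6 libraries in a comparison called up to 30, 27 and 28 lists. With an estimated correlation camera called 0, 1 and 0, and fry called 23, 10 and 31.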

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

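The fits without mitochondrial genes, with other pseudocounts, with a plain variance model and with pairs of libraries per group were chosen after seeing the data. No called list reversed its direction under median-of-ratios scaling, the filters or the pseudocounts, and where still tested no named gene did under these or upper quartile scaling. Counts are given for Co+Len@OVA+anti-PD1 against Control, Lenvatinib+anti-PD1 against Control, the treatments against each other, any difference among the groups, and genes shared in direction, where they moved over 1.5 times from 5155, 3636, 4507, 6935 and 1652. Libraries 1 and 2 of each group gave 80, 53, 365, 305 and 14. Libraries 1 and 3 gave 1913 for Lenvatinib+anti-PD1 against Control and 838 shared genes. Libraries 2 and 3 gave 4452, 4748 and 5027, within 1.5 times. The cause of these differences between pairs was not tested. A 2-fold minimum gave 1223, 653 and 1352, with 146 shared. A mean of at least 5 FPKM, which tests fewer genes, gave 3020, 2705 between the treatments and 4188 for any difference. Fits of only the groups compared gave 3279 for Co+Len@OVA+anti-PD1 against Control and 1041 shared. Between the treatments they gave 6229, within 1.5 times. The single fit pools the spread of all 3 groups, which was unequal. The median SD on the log2 scale was 0.175 in Control, 0.123 in Co+Len@OVA+anti-PD1 and 0.091 in Lenvatinib+anti-PD1. How far this accounts for the changed counts was not tested.

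Leaving out each library gave 2849 to 5770, 1957 to 5053, 2381 to 6592, 4280 to 8217 and 888 to 1794. Counts moved over 1.5 times without Co+Len@OVA+anti-PD1 replicate 3 (2849, 2381 between the treatments, 4280 for any difference, 952 shared), without Lenvatinib+anti-PD1 replicate 3 (1957, 2525 between the treatments, 888 shared), replicate 2 (2410, 1063 shared) or replicate 1 (2900 between the treatments), and without Control replicate 3 (2138, 925 shared). Over lists and omitted libraries, 29 of the list calls were lost and 646 held. Among them was the adipocyte list in Lenvatinib+anti-PD1, which also lost its call with libraries 1 and 2 alone (adjusted p = 0.0609). Of the 75 list calls, 74 were lost with an estimated correlation and 18 with fry. Of the named genes' tests, 336 lost their call with libraries 1 and 2 alone. The other 131 were the same, which includes tests that passed in neither fit.

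The replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.25 to 0.08. With a replicate block 4025, 2753 and 3307 genes passed, 5294 for any difference and 1200 shared. DESeq2 and limma-voom were not run, since they need counts. Depth is only estimated, so its effect on low genes was not tested.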

Other observations

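Tests of the third libraries against weighted means, of Kupffer and sinusoidal markers, of scaling, and of NRF2, HIF and haemoglobin genes were chosen after the result was seen. The count of V(D)J segments was also chosen after its pattern was seen, with its bounds recorded before the count was made, and the splits of the libraries were chosen before the data were examined.

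Markers of tissues outside the tumour differed between libraries of a group. The neural genes, a list added once the data had been seen, had a median of 10.2 FPKM in Co+Len@OVA+anti-PD1 library 1, 0.21 in library 2 and 5.55 in library 3, and at most 0.32 elsewhere. Krt12, a keratin of the corneal epithelium chosen after its values were seen, ranged from 0.055 FPKM in Control library 2 to 179 in Lenvatinib+anti-PD1 library 2. Xist, expressed from the inactive X chromosome, was at 22.9 to 32.3 FPKM in all 9 libraries, and the Y-linked Ddx3y was at 1.64 to 3.85 FPKM in the same libraries. No explanation of these values was tested.

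The third library of each group lay near a weighted mean of the other 2, and this was examined in 4 ways, all devised once the pattern had been seen. Chance order of independent libraries stays open where genes vary together. At least 94.0% of genes over 4-fold apart had the third library in between. An independent library, however, also tends to fall between values picked for being far apart. Over all genes, the third library lay between the others for 45.2% to 66.5%, against 12.3% to 30.0% for libraries 1 and 2. These shares argue against a chance order in genes that vary separately. Genes vary together, so the shares do not settle it. An independent mouse on a shared axis of tissue composition stays open. V(D)J segments, whose use was assumed to be particular to each animal, were highest by over 2-fold in the third libraries for 6 segments. The mean was 11 in libraries 1 and 2, and 6 lay between the bounds recorded before the count was made. By group the third libraries had 0 (Co+Len@OVA+anti-PD1), 5 (Lenvatinib+anti-PD1) and 1 (Control). The assumption was not tested, and the segment Igkv12-46 was at 58.4 to 70.9 FPKM in all 3 Co+Len@OVA+anti-PD1 libraries, against 1.65 to 1.78 in Lenvatinib+anti-PD1. Material shared between libraries stays open: the share of library 1 estimated from genes higher in either library differed by -0.02 in Co+Len@OVA+anti-PD1 (255 and 23 genes) and 0.03 in Control (90 and 260 genes), inside the bound of 0.1, and by -0.39 in Lenvatinib+anti-PD1, which rests on 6 genes, under a minimum of 10 set once this value had been seen, while Krt12 in the third library lay between the others in Co+Len@OVA+anti-PD1 (43.4 FPKM against 34.6 and 57.8) and outside them in Lenvatinib+anti-PD1 (32.7 against 112 and 179) and Control (147 against 44.9 and 0.055). Scatter around the weighted mean was at most 1.34 times the counting error, which decides nothing, because its bound of 1.5 was set after similar values had been seen and the depth is estimated.

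Mature hepatocyte genes were lower in Co+Len@OVA+anti-PD1 than in Lenvatinib+anti-PD1. Composition of the FPKM totals is argued against, since it would shift all genes of a library alike. The median log2 fold change of all genes was 0.074 as deposited and -0.006 under median-of-ratios scaling. The list median was -3.92 under that scaling, which could hardly have moved it. Less liver tissue in the pieces may contribute and stays open. The joint median of 19 Kupffer and sinusoidal markers was 0.12, which by a bound recorded after the hepatocyte result would argue against it. They went both ways, however (quartiles -0.85 and 1.29), and the liver-restricted Clec4f fell from 8.06 ± 0.36 to 0.15 ± 0.06 FPKM. Cd5l, outside the naming rule, Clec4g and Vsig4 had log2 fold changes of -2.16, -1.58 and -1.56. Those of Marco, Fcgr2b, Mrc1 and Stab1 were 2.13, 1.61, 1.56 and 1.55. Mrc1 and Stab1 are also on the list of alternatively activated macrophage genes, so the joint median does not follow liver tissue alone. An effect of the treatment on hepatocyte genes was not tested separately and is also open. Differing liver tissue was not tested for the comparisons with Control and stays open there too. Clec4f was at 2.72 to 3.51 FPKM in Control, between the values of the treatments. Of 10 Kupffer cell markers, 3 rose and 2 fell in Co+Len@OVA+anti-PD1 against Control.

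Hmox1 was higher in Co+Len@OVA+anti-PD1 than in both other groups. General activation of NRF2 targets stays open: the 31 other list genes went both ways. Against Lenvatinib+anti-PD1 6 rose and 13 fell, with a median of -0.17 (quartiles -1.10 and 0.20). Their median was 0.03 against Control (-0.52 and 0.31), and the list holds detoxification genes that hepatocytes express. General activation of HIF targets is argued against for the rise over Control by their median of -0.30 there (quartiles -0.62 and -0.04), while against Lenvatinib+anti-PD1 their median was 0.15, with 9 risen and 2 fallen (fry adjusted p = 0.00479, camera 0.153), so a part in that rise stays open. More blood in the pieces may be a candidate explanation: summed haemoglobin FPKM in the lowest Co+Len@OVA+anti-PD1 library was 3.43 times that in the highest other library, and each of the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt was higher in all 3. An effect of the nanocluster moves with the same groups and stays open as untested.

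For any difference among the groups, 1 of 100 drawn splits, the real one, gave as many genes as 6935, and the highest other gave 2440, but this does not exclude chance: the third libraries lie near a mean of the other 2 of their own group, and splits that keep a group whole call more genes (316 to 2440 in the 9 drawn that keep 1 group whole, against 0 to 3 in the 90 that keep none). Simulations of such libraries with no group effect called a mean of 1138 genes in a comparison. The 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 5155, 3636 and 4507 genes and the highest others 0, 2 and 0, with 1 split as large in each. Of the list counts, 4 of 10 splits gave at least the 24 of Co+Len@OVA+anti-PD1 against Control (highest other 30), 6 at least the 21 of Lenvatinib+anti-PD1 against Control (highest other 27), and 1 the 30 between the treatments (highest other 28).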
